A study of Mus musculus with 2 samples.

How the data were processed

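Total RNA from 2 embryonic day 14.5 mouse kidney samples (strain B6NCrl, 2 kidneys of 1 embryo each) was sequenced. Per the labels, RNA was extracted with a mirVana kit, the RNA was longer than 200 nt, 10 ng entered each library, spike-in RNAs were added, and the linked general protocol is a Smart-seq method. The labels number the samples as biological replicates 1 and 2 of 1 condition and give collection days 2 days apart. They also call each sample a pool of both sexes while describing it as kidneys of a single pup.

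Reads were quantified by the submitters against mm10, per the labels. The quantification tool and aligner are not given in the sources used here; the column headers are those that RSEM writes. Per the file headers, each library has a gene table and a transcript table. The deposited expected counts are estimated numbers of reads per gene or transcript and are not whole, because reads that match several features are shared out. The deposited TPM values are transcript abundances scaled to a fixed sum over all features, spike-ins included, both as maximum likelihood and as posterior mean estimates. The deposited FPKM values are fragments scaled to effective length and library depth. The deposited bounds of a credibility interval of each TPM, a signal on the TPM scale, describe the estimate within 1 library, at a level that is not given. The deposited isoform percent is the share of a gene's TPM taken by each transcript. Length and effective length, in nt, come from the same tables, and those of genes are weighted by transcript abundance. Whether counting used strand is not given in the sources used here, so antisense pairs such as Xist and Tsix cannot be told apart with certainty.

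Each gene table held 69691 features: 43346 genes, 96 ERCC spike-ins, 1 phiX sequence with 0 counts, and 26248 features named only by a number, which were left out of all tests. Symbols, gene types, coordinates and exons were taken from GENCODE release M21 on GRCm38, the same assembly as mm10 but another annotation release than that of the tables, so transcript structures can differ; 42462 gene IDs matched and 884 did not, the latter holding 0.211 and 0.193 percent of gene counts. Coordinates are 1-based.

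The depth was 29718428 and 29204212 expected counts. Intervals of shares are Clopper-Pearson 95% intervals, intervals of ratios between libraries are exact conditional binomial intervals, and a count of 0 was taken to allow up to 3 counts. The reads carry no molecular identifiers that are used here, so these intervals and limits cover counting error only.

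Detection was set at 1 TPM in both libraries. Agreement was described by Pearson's r and Spearman's rho of log2(TPM + 1). Dispersion was estimated with edgeR 4.0.16 in R 4.3.3 on expected counts rounded to whole numbers, with an intercept-only design, TMM factors and filterByExpr. With 2 samples of 1 group no gene can be tested. Genes apart between libraries were those with an absolute log2((TPM + 1) ratio) of at least 1 and at least 5 TPM in the higher library; the pseudocount understates differences of low genes. The 34 gene lists were fixed before the data were examined, with 497 matched members; 3 members (Ahsp, Rn45s and Snhg1) found no match, and Rn18s-rs5 was matched as Gm42418. For each list the median over members of the mean TPM was taken, and the median log2 ratio of members at a mean of 1 TPM or more was ranked among 10000 random lists of the same size drawn from 15075 genes in 20 bins of expression. Splice choices of Wt1, Fgfr2 and Pkm were summed over transcripts that contain the exon in question. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

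The rule for naming genes was set before the data were examined: up to 4 highest and 2 lowest members of each list, the 15 highest nuclear protein-coding genes outside the ribosomal proteins, the 10 largest differences between libraries in each direction (unnamed gene models passed over), 13 genes with isoforms of interest, the sex-linked lists, and 14 further kidney genes. Exceptions are stated beside the gene.

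The scripts were tested on simulated libraries with the real means and sizes. A simulated coefficient of variation of 0.20 was recovered as 0.198 over unchanged genes and as 0.228 over all 16665 tested, which include the genes simulated at 3-fold and 6-fold. The size rule called 82% of 100 genes simulated at 3-fold, 98% of 100 at 6-fold and 1.32% of 11145 unchanged genes. Of 100 simulated unchanged lists of 15 genes, 2% fell outside the central 95% of random lists, and 100% of lists shifted by 0.50 log2 units fell below it. The simulated genes varied independently and without a trend over length. These rates therefore need not hold for the real libraries, or for lists whose members vary together.

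Alternatives covered detection floors, pseudocounts, FPKM, posterior mean TPM, TPM rescaled without mitochondrial, haemoglobin and spike-in features, TMM-scaled CPM (counts scaled to library depth), spike-in scaling, DESeq2 1.42.0 size factors and dispersion, filters on low counts and leaving out each replicate. Length-matched random lists, subtraction of the length trend, a filter on short or low genes, protein-coding genes alone and single Y-linked genes were added after the data had been seen.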

Results

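Total RNA was sequenced from mouse kidneys at embryonic day 14.5, when nephrons are forming at the tips of a branching ureteric tree. Each of the 2 libraries was made from 2 kidneys of 1 embryo of strain B6NCrl, starting from 10 ng of RNA longer than 200 nt, and the embryos were collected 2 days apart. The libraries are biological replicates of 1 group, so the data give levels in the tissue and the spread between replicates, and no second condition was compared. The deposited tables held 29718428 expected counts for replicate 1 and 29204212 for replicate 2, of which 28429080 and 27758872 fell on genes. Levels below are in TPM (transcript abundance scaled to a fixed sum per library) as mean ± SD (n = 2) unless both library values are given, in which case replicate 1 comes first. A list median is the median over members of their mean levels, followed in parentheses by the medians within replicates 1 and 2, which need not lie on either side of it.

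Among nuclear protein-coding genes outside the ribosomal proteins, Actb (cytoplasmic actin) stood highest at 5519 ± 223 TPM, Ppia (cyclophilin A) at 5277 ± 673 TPM, Hba-a2 (adult-type alpha globin) at 5064 ± 658 TPM and Eef1a1 (translation elongation factor) at 4692 ± 585 TPM. Next among the 15 highest of these genes were the histone gene Hist1h2ap at 4354 ± 939 TPM, the ferritin light chain Ftl1 at 3188 ± 115 TPM, Ptma at 3045 ± 249 TPM, Ubb at 2508 ± 79.1 TPM and Hmgn2 at 2461 ± 124 TPM. The remaining 6 were Hbb-bs, H3f3a, H2afz, Hspa8, Atp5b and Tmsb10, between 1993 and 2373 TPM. The pairs Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, and the clustered histone genes are near-identical copies, so the split of counts within them is uncertain.

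14329 genes reached 1 TPM in both libraries, and 12669 of them were among the 21474 protein-coding genes of the table. A further 896 genes reached 1 TPM in replicate 1 alone and 477 in replicate 2 alone. Mitochondrially encoded genes took 2.46% ± 0.598 of the counts on genes (SD, n = 2), ribosomal protein genes 3.5977% ± 0.807, haemoglobin genes 0.437% ± 0.00344, and the 10 most abundant genes together 6.73% ± 1.31. Added spike-in RNAs took 4.34% of all counts in replicate 1 (Clopper-Pearson 95% interval 4.33 to 4.35%) and 4.95% in replicate 2 (4.94 to 4.96%). On TPM the shares were equal, at 9.56% and 9.56%.

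Nephron progenitors of the cap mesenchyme were strongly represented. Cited1, a transcriptional co-activator of uncommitted progenitors, stood at 136 ± 6.92 TPM and Wt1, a zinc-finger regulator of progenitors and podocytes, at 105 ± 33.4 TPM. Crym reached 70.4 ± 5.30 TPM and Eya1, a phosphatase and co-activator that nephron progenitors require, 62.4 ± 14.3 TPM. Six2, the transcription factor that holds progenitors in the self-renewing state, was lower at 17.6 ± 2.40 TPM, and Pax2 stood at 38.3 ± 8.27 TPM. Six2 (ENSMUSG00000024134.11) lies on mm10 chromosome 17, 85684277 to 85688274, Cited1 (ENSMUSG00000051159.12) on chromosome X, 102247381 to 102252181 and Wt1 (ENSMUSG00000016458.9) on chromosome 2, 105126529 to 105173616. In all, 16 of 17 members of the progenitor list were detected with a list median of 28.0 TPM (35.2 and 30.1 TPM). Dapl1 was among the lowest members at 4.8 ± 1.29 TPM.

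Markers of the renal vesicle and early nephron were detected for 14 of 14 genes, with a list median of 18.8 TPM (20.1 and 15.4 TPM). The cyclin gene Ccnd1 led at 197 ± 53.3 TPM, followed by Pax8, a transcription factor of the induced nephron, at 89.7 ± 29.2 TPM, and the Notch ligand Jag1 stood at 35.8 ± 11.9 TPM. Wnt4, the signal that drives the mesenchymal-to-epithelial transition, stood at 14.3 ± 2.43 TPM. Pou3f3 at 6.64 ± 0.417 TPM and Greb1 at 5.67 ± 1.36 TPM were the lowest.

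Lists of maturing nephron segments had lower medians than that of the early nephron. In the list of podocytes, the filtration cells of the glomerulus, Tcf21 (also a stromal transcription factor) had a tissue level of 274 ± 21.1 TPM. Foxc2 stood at 38.7 ± 3.53 TPM, Cd2ap at 30.5 ± 9.42 TPM and Podxl at 29.1 ± 4.48 TPM. Nphs1, which encodes the slit diaphragm protein nephrin, was at 2.61 ± 0.0566 TPM, and the mature glomerular collagen chains Col4a3 and Col4a4 were at 0.745 ± 0.332 TPM and 0.595 ± 0.276 TPM. The podocyte list median was 4.71 TPM (6.61 and 2.81 TPM), with 15 of 17 members detected.

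Proximal tubule genes had a list median of 3.43 TPM (4.17 and 2.01 TPM) and 12 of 20 members detected. Among the highest were the scaffold Pdzk1 at 37.9 ± 16.2 TPM, the phosphate transporter Slc34a1 at 14.7 ± 9.45 TPM and the urea-cycle enzyme Ass1 at 13.1 ± 3.97 TPM, while the transcription factor Hnf4a was at 6.48 ± 2.76 TPM. Slc5a12 had 11 and 3 counts. Kap, an abundant gene of the adult proximal tubule, had 0 counts in both libraries, which allows up to 0.302 and 0.262 TPM at 3 counts each. In the loop of Henle and distal tubule list, 9 of 14 members were detected and the median was 1.98 TPM (2.11 and 1.45 TPM). Tfap2b stood at 31.6 ± 0.643 TPM, the sodium-potassium-chloride cotransporter Slc12a1 at 11.4 ± 7.66 TPM and Cldn10 at 7.43 ± 2.93 TPM. Umod (uromodulin) was at 1.12 ± 0.368 TPM, Slc12a3 (the distal thiazide-sensitive cotransporter) at 0.105 ± 0.00707 TPM, and Pvalb had 0 counts, which allows up to 0.178 and 0.154 TPM.

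The ureteric tree was represented by both its tips and its trunk. All 10 tip genes were detected with a median of 28.0 TPM (27.4 and 27.5 TPM). The ETS factors Etv5 and Etv4, targets of GDNF signalling, stood at 42.8 ± 15.1 TPM and 38.6 ± 3.94 TPM, the GDNF co-receptor Gfra1 at 41.3 ± 18.3 TPM and the feedback inhibitor Spry1 at 35.2 ± 5.57 TPM. Ret (ENSMUSG00000030110.9, chromosome 6, 118151745 to 118197718), the receptor through which GDNF acts, was at 8.06 ± 4.24 TPM, with 11.1 TPM in replicate 1 and 5.07 TPM in replicate 2. Sox8 and Ros1 were the lowest members at 5.88 ± 1.45 TPM and 3.31 ± 0.799 TPM.

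In the trunk and collecting duct list 19 of 19 members were detected with a median of 9.96 TPM (11.6 and 9.94 TPM). The calcium-binding protein Calb1 was at 166 ± 2.47 TPM, and the keratins Krt8 and Krt18 were at 152 ± 7.96 TPM and 120.0 ± 17.2 TPM. Aqp2, the vasopressin-regulated water channel of principal cells, was at 3.54 ± 1.05 TPM, so that Calb1 exceeded it 49.1 ± 15.2-fold (SD, n = 2). Atp6v1b1, a proton pump subunit of intercalated cells, and the urothelial Upk1b were at 1.78 ± 0.0990 TPM and 1.4 ± 0.141 TPM.

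Stromal genes had the highest median of the cell type lists of the kidney, 57.4 TPM (63.3 and 41.4 TPM), with 19 of 19 members detected. The fibrillar collagen genes Col3a1 and Col1a1 stood at 414 ± 78.4 TPM and 242 ± 80.0 TPM, the retinoic acid-synthesising enzyme Aldh1a2 at 272 ± 60.4 TPM and Penk at 179 ± 20.6 TPM. Foxd1, the marker of cortical stromal progenitors, was at 15.3 ± 4.17 TPM, and Tbx18 at 2.54 ± 0.134 TPM was the lowest. Among the 11 smooth muscle, mural and renin cell genes 10 were detected. Acta2 (smooth muscle actin) was at 76.6 ± 30.4 TPM, Ren1 (renin) at 55.1 ± 24.6 TPM, Des at 34.985 ± 3.92 TPM and Mcam at 25.5 ± 8.12 TPM, while the markers of mature contractile muscle Cnn1 and Myh11 were at 2.19 ± 0.580 TPM and 1.68 ± 1.46 TPM.

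Vessels and blood cells were also captured. All 16 endothelial genes were detected with a median of 27.9 TPM (31.4 and 24.6 TPM), led by Egfl7 at 141 ± 7.64 TPM, the fenestral diaphragm gene Plvap at 91.1 ± 6.83 TPM, Emcn at 69.3 ± 5.67 TPM and the tight junction gene Cldn5 at 57.9 ± 10.5 TPM; Erg was the lowest at 4.07 ± 0.898 TPM. Macrophage and leukocyte genes were detected for 13 of 14 members at a median of 7.77 TPM (8.98 and 7.04 TPM), with Lyz2 at 34.6 ± 10.4 TPM, the complement gene C1qb at 29.2 ± 1.93 TPM, Tyrobp at 19.3 ± 0.948 TPM and the lowest, Fcgr1, at 1.08 ± 0.247 TPM. Globin messages were abundant while that of an erythroid regulator was not. Hba-a2, Hbb-bs, Hba-a1 and Hbb-bt lay between 1869 and 5064 TPM, against 0.39 ± 0.0141 TPM for the erythroid regulator Gata1.

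**Figure D1:**
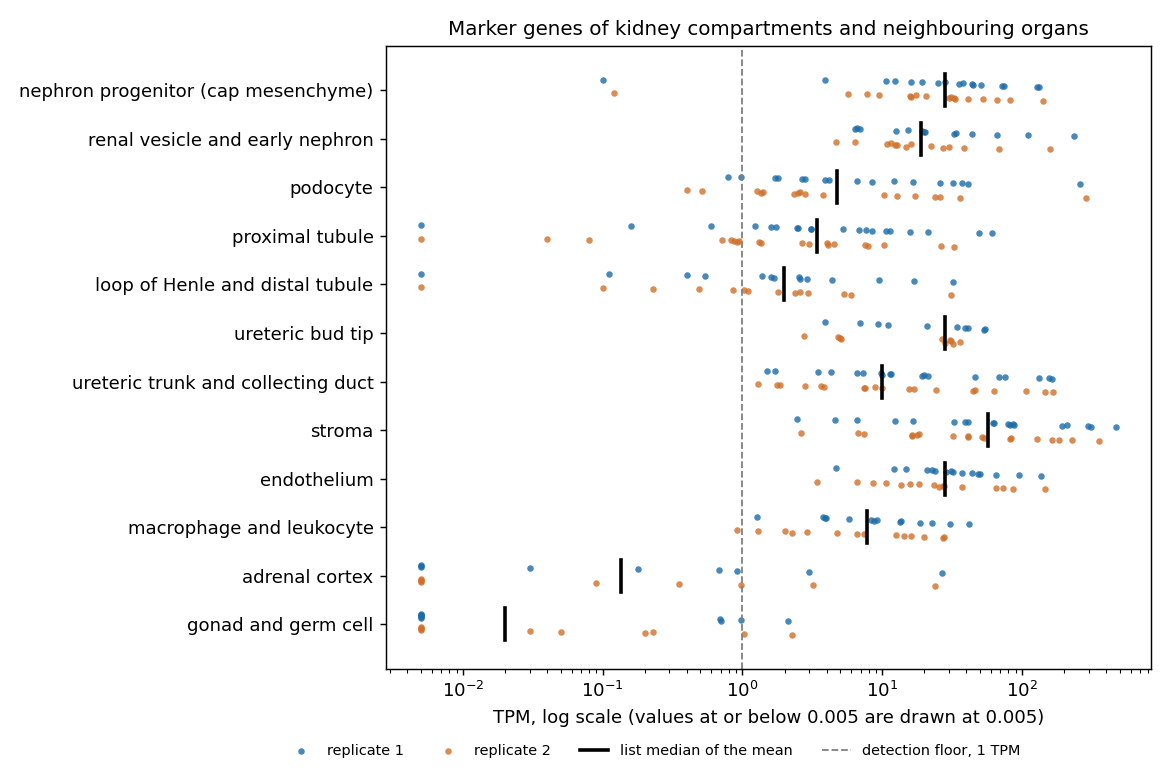
Levels of the marker genes of 12 lists in both E14.5 kidney libraries. Each point is 1 gene in 1 library, with TPM on a log axis, the black bars mark the list medians of the mean of both libraries and the dashed line marks 1 TPM. Stromal markers had a median of 57.4 TPM, proximal tubule markers 3.43 TPM and adrenal cortex markers 0.135 TPM.

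Markers of organs that neighbour the kidney or could be carried along in dissection were mostly below 1 TPM. Of the adrenal cortex list 2 of 9 members were detected, Akr1b7 at 25.3 ± 1.82 TPM and Mc2r (the corticotropin receptor) at 3.1 ± 0.127 TPM, while Star was at 0.945 ± 0.0354 TPM and Cyp11a1, the first enzyme of steroid synthesis, at 0.515 ± 0.233 TPM. Of the adrenal medulla and sympathetic neuron list 2 of 10 were detected, with Ddc highest at 6.05 ± 0.940 TPM. The gonad and germ cell list had 1 of 10 detected, Inha at 2.19 ± 0.0990 TPM. Of the liver list 5 of 10 were detected, with Afp (alpha-fetoprotein) at 17.5 ± 6.36 TPM and Serpina1a at 4.66 ± 1.71 TPM. Skeletal muscle gave 3 of 10, led by Tnni1 at 14.6 ± 0.467 TPM and Mylpf at 7.54 ± 0.247 TPM, and neurons and Schwann cells gave 5 of 12, led by Elavl4 at 11.7 ± 2.24 TPM and Stmn2 at 5.07 ± 0.587 TPM. Levels in whole tissue do not tell whether the detected members came from such organs or from the kidney itself.

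Early and mature chains of the basement membrane differed widely in level. Col4a1 stood at 160.2 ± 71.5 TPM, Lamc1 at 102 ± 24.8 TPM, Lamb1 at 85.3 ± 25.8 TPM and the heparan sulphate proteoglycan Agrn at 56.1 ± 14.1 TPM, and 14 of 17 members of the list were detected. Col4a1 exceeded Col4a3, a chain of the mature glomerular membrane, 215-fold in replicate 1 and 215-fold in replicate 2. Lamb1 exceeded Lamb2, the laminin chain that replaces it in mature glomeruli, 4.28-fold and 4.16-fold. Lama5, a chain of the mature glomerulus, in contrast exceeded the early chain Lama1, 1.54-fold and 2.48-fold. Lamb2, Lama5 and Lama1 were chosen after their values were seen. Of the branching signals and receptors 22 of 25 were detected with a median of 13.2 TPM (16.5 and 7.77 TPM). The receptors Fgfr1, Fgfr2 and Robo2 led at 81.4 ± 22.9 TPM, 79.0 ± 42.2 TPM and 75.0 ± 26.4 TPM, and Wnt2b and the BMP antagonist Grem1 were at 0.375 ± 0.0354 TPM and 0.185 ± 0.0778 TPM.

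In the renin-angiotensin and erythropoietin list 6 of 10 members were detected. Besides Ren1, the peptidase gene Enpep was at 42.8 ± 12.8 TPM and the type 2 angiotensin receptor gene Agtr2 at 31.5 ± 2.76 TPM. The type 1 receptor gene Agtr1b was at 0.20 ± 0.0424 TPM. Epo (erythropoietin) had 1.02 counts in replicate 1 and 0 in replicate 2, so expression was not detectable at this depth.

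Hox genes, which set the position of the kidney along the body axis, had their highest summed levels in paralog groups 9 to 11. These 3 groups held 57.0% ± 2.32 of the summed Hox level (SD, n = 2), with Hoxa10 at 139.9 ± 9.67 TPM, Hoxa9 at 50.015 ± 6.50 TPM and Hoxc10 at 48.9 ± 0.827 TPM. The groups differ in their number of genes, so the sums do not rank levels per gene. Group 11 summed to 69.9 ± 6.92 TPM over 3 genes and group 7 to 62.9 ± 0.156 TPM over 2. Hoxb7, of the ureteric bud, was at 46.2 ± 0.226 TPM. The 4 genes of paralog group 13 together reached 0.19 and 0.26 TPM, and Hoxb13, Hoxc12 and Hoxc13 had 0 counts in both libraries. In all, 32 of 39 Hox genes were detected.

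**Figure D2:**
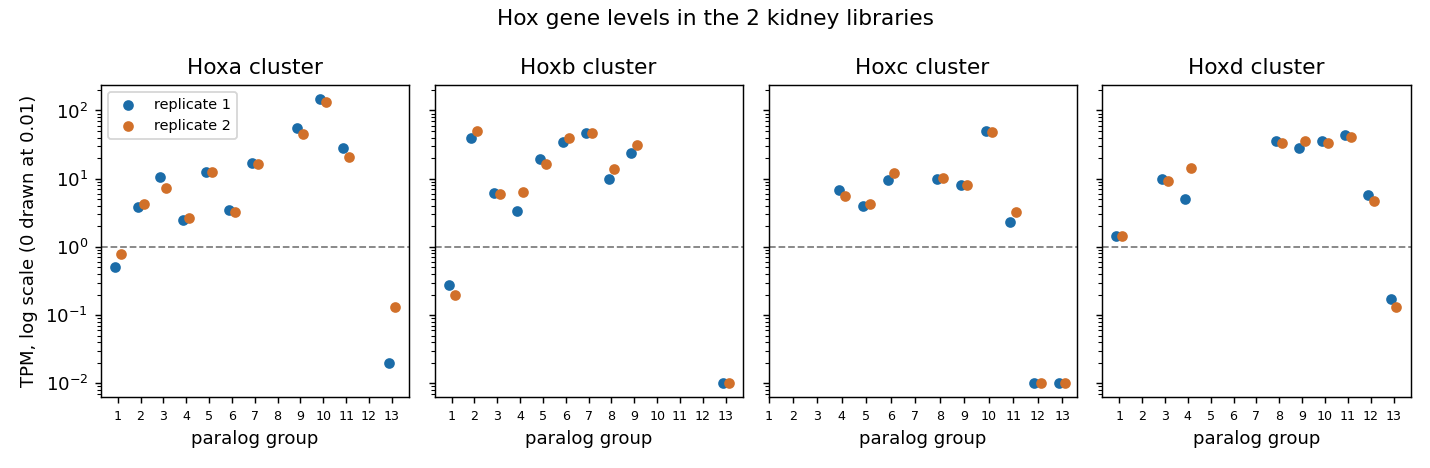
Level of each Hox gene in both libraries, 1 panel per cluster, with the paralog group on the x axis and TPM on a log y axis (0 drawn at 0.01, dashed line at 1 TPM). The highest point is Hoxa10 at 147 and 133 TPM, and the group 13 genes sum to 0.19 and 0.26 TPM.

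Cell cycle genes were high. All 20 proliferation genes were detected with a median of 165 TPM (179.7 and 141 TPM). The ubiquitin-conjugating enzyme gene Ube2c was at 478 ± 53.1 TPM, the mitotic kinase Cdk1 at 429.5 ± 4.43 TPM, Birc5 at 295 ± 28.0 TPM, Pcna at 276 ± 13.6 TPM and Mki67 at 45.1 ± 10.4 TPM. Imprinted genes were detected for 22 of 23 members, with Mest at 1933 ± 253 TPM, Gnas at 1148 ± 132 TPM, the cell cycle inhibitor Cdkn1c at 761 ± 83.4 TPM and the growth factor Igf2 at 505 ± 66.4 TPM; Rtl1 was at 0.35 ± 0.0990 TPM. Glycolytic genes of the HIF list were led by Eno1 at 1281 ± 125 TPM, Ldha at 1039 ± 81.8 TPM and Aldoa at 526 ± 21.7 TPM, whereas the hypoxia-induced Adm and Car9 were at 3.56 ± 0.346 TPM and 0.79 ± 0.226 TPM. Immediate early and heat shock genes had a median of 8.47 TPM (9.82 and 7.12 TPM), with Ier2 at 65.5 ± 1.57 TPM and Dnajb1 at 46.8 ± 6.27 TPM at the top and Hspa1b and Fosb at 0.515 ± 0.120 TPM and 0.080 ± 0.0283 TPM at the bottom.

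Mesenchymal and epithelial genes were both well represented, all 17 of the list being detected. Vim (vimentin) was at 359.9 ± 34.6 TPM, Epcam at 169 ± 11.1 TPM and Cldn6 at 124 ± 19.6 TPM, and the lowest were Twist1 at 5.67 ± 1.53 TPM and Esrp2, an epithelial splicing factor, at 5.63 ± 2.09 TPM. All 12 housekeeping genes were detected, from Tfrc at 38.5 ± 14.043 TPM and Tbp at 49.4 ± 3.42 TPM to Actb.

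Splice choices with known tissue roles were close between the libraries. Wt1 transcripts with the longer exon that adds 3 amino acids (KTS) between zinc fingers (mm10 chromosome 2, 105169926 to 105170018, 93 nt, coding) held 78.2% ± 0.0254 (SD, n = 2) of the level of transcripts with either form, the remainder carrying the form that is 9 nt shorter. Pkm was almost wholly of the M2 form of pyruvate kinase, with 96.7% ± 0.145 from the transcript with the coding exon at chromosome 9, 59675568 to 59675734, against that with the exon at 59675029 to 59675195. Fgfr2 transcripts with either exon divided between the epithelial IIIb exon (chromosome 7, 130199758 to 130199905) at 47.4% ± 3.06 and the mesenchymal IIIc exon (130198419 to 130198563) at 52.6%. Transcripts with either exon held 20.2 and 24.4 TPM in replicate 1 and 6.89 and 7 TPM in replicate 2, and the Fgfr2 transcript with the highest level, at 42.3% ± 11.6 of the gene, carried neither. The IIIb level includes Fgfr2-211 at 9.85 and 3.55 TPM, whose length in the tables differs from that in the reference used to assign exons, so the IIIb share is an upper estimate if that transcript lacked the exon. The same difference applies to the transcript that stands for the M1 form of Pkm.

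Across 7589 genes with at least 2 annotated transcripts and 5 TPM in both libraries, the same transcript led in both libraries for 89.2 percent, and the median share of the leading transcript was 69.4% ± 0.131 (SD, n = 2). Pax8 was led by 1 transcript at 69.8% ± 5.70, Gnas at 77.5% ± 1.71, Tpm1 at 44.4% ± 1.28 and Pax2 at 44.2% ± 6.17. Fn1 (fibronectin) differed between libraries: its 8315-nt coding transcript took 42.6% in replicate 1 and 13.3% in replicate 2, and a 4022-nt transcript with a retained intron took 33.3% in replicate 1 and 53.0% in replicate 2. Ctnnd1, of adherens junctions, likewise changed its leading transcript, Ctnnd1-206 taking 9.77% in replicate 1 and 48.5% in replicate 2. Among the 820 genes whose leading transcript differed, that of replicate 2 was the shorter in 505, the longer in 314 and of equal length in 1. These are estimated shares in 1 library each, and the cause of the differences was not tested.

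The 2 libraries gave closely similar levels for most genes. Pearson's r of log2(TPM + 1) was 0.968 and Spearman's rho 0.969 across 15702 genes at 1 TPM or more in at least 1 library; genes are not independent replicates. The biological coefficient of variation, as edgeR names it, was 0.222 over 16526 genes, 0.253 in the lower and 0.208 in the upper range of abundance. The length trend described below was not removed from it, so it does not measure variation between embryos alone. The median log2 ratio of replicate 2 to replicate 1 over genes at a mean of 1 TPM or more was -0.26, and differences of gene lists are to be read against that value. There is no test between the libraries, since each stands alone.

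By the size rule of a 2-fold difference and 5 TPM in the higher library, 638 genes differed, 115 higher and 523 lower in replicate 2. With TMM-scaled CPM in place of TPM the split was 131 higher and 109 lower. The largest differences were in sex-linked genes, whose values are given with the closing observations. Arpc3, a subunit of the actin-nucleating Arp2/3 complex, stood at 25.4 TPM in replicate 1 and 152 TPM in replicate 2, a ratio of 6.0024 with an interval from the scaled counts of 5.61 to 7.01. The rest of the 10 largest in each direction were small nucleolar RNAs, microRNA precursors, an rRNA copy and 2 pseudogenes (Hist1h2aj and Rpl21-ps15), with 0 counts in 1 of the libraries; 24 unnamed models were passed over among the lower and 23 among the higher. Of the 638 genes, 103 had an effective length under 200 nt or fewer than 20 counts in the libraries together.

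The difference between libraries followed transcript length. Protein-coding genes of 400 to 600 nt had a median log2 ratio of 0.35 (SD 0.33 over 214 genes), those of 1000 to 1500 nt -0.00216 (SD 0.36, 1622 genes) and those of 4000 to 6000 nt -0.65 (SD 0.42, 1809 genes), with no further change in longer genes (-0.60 at 6000 to 10000 nt). Across 12663 protein-coding genes Spearman's rho with length was -0.57. Over the range of spike-in lengths, 274 to 1994 nt, the gene slope was -0.267 log2 units per doubling of length (95% bootstrap interval -0.287 to -0.244), and the slope of 46 spike-in RNAs, of the same set in both samples per the labels, was -0.205 (-0.293 to -0.115).

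**Figure D3:**
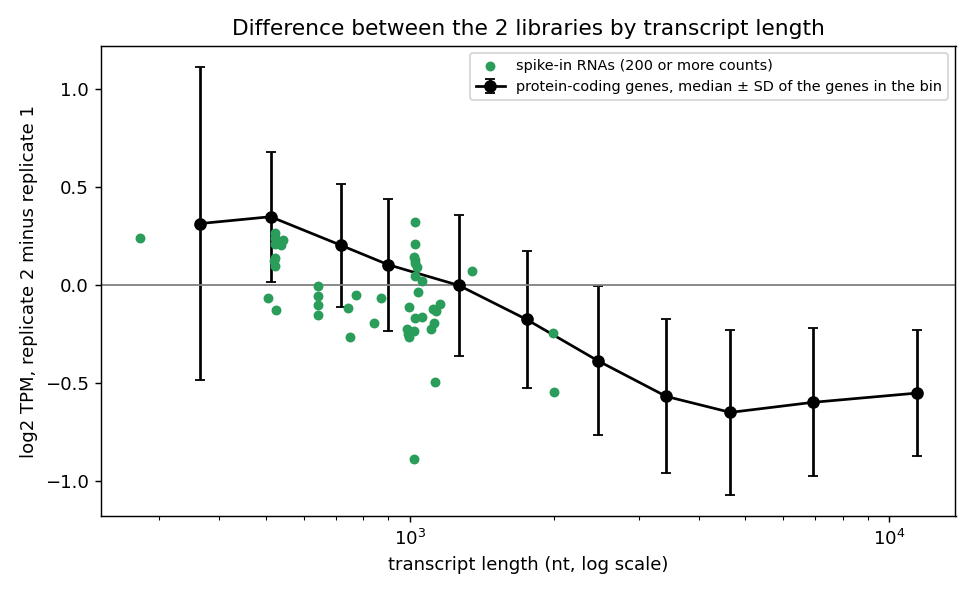
Log2 ratio of TPM in replicate 2 to replicate 1 against transcript length in nt on a log axis. Black points are medians of protein-coding genes in length bins with the SD of the genes as bars, and green points are spike-in RNAs. The bin medians go from 0.35 at 400 to 600 nt to -0.65 at 4000 to 6000 nt.

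Among 28 gene lists with at least 5 members at 1 TPM, 6 had a median difference outside the central 95% of 10000 random lists. The random lists were of like expression, and 3 lists lay below and 3 above. By chance 1.4 would be expected if list members varied independently, which genes of a cell type or family need not do. Proximal tubule genes stood lowest, with a median log2 ratio of -0.82 and 17 of 17 members lower in replicate 2. Slc34a1 stood at 21.3 and 7.97 TPM and Pdzk1 at 49.3 and 26.4 TPM, replicate 1 first, and none of the random lists lay as low. Basement membrane chains (median -0.56, percentile 1.08) and branching signals and receptors (median -0.54, percentile 1.16) were also low, but against random lists matched on length as well as expression, an alternative chosen after the trend was seen, they stood at percentiles 55.6 and 17.9. Hox genes (median -0.00287, percentile 99.98), replication-dependent histones (median 0.40) and small non-coding RNAs (median 0.88, both at percentile 100) stood high, and stayed above the central 95% against length-matched lists (99.96, 99.5 and 100). The nephron progenitor list stood at percentile 43.4 and the podocyte list at 39.1, within the central range.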

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

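Counts on features outside the genes stood out because they exceeded the 3 counts that a count of 0 allows. The 26248 features named only by a number, 26185 of them at most 100 nt long and with a median length of 73 nt, held 28 counts over 6 features in replicate 1 and 29.4 counts over 8 features in replicate 2. What these features are was not analysed here.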

How the results depend on the processing

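The number of genes detected stayed within 1.5 times the value of 14329 under every alternative run, from 10409 at a floor of 5 TPM to 19454 at 0.1 TPM. The number of list members detected, 396, ranged from 303 to 456, and the Y-linked level of the lower library stayed under 1% of the higher under all settings run.

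Pearson's r of 0.968 became 0.934 with a pseudocount of 0.1, 0.988 with no floor, 0.957 with a floor of 5 TPM and 0.980 with CPM. The coefficient of variation of 0.222 became 0.243 with no filter on low counts and 0.237 with the DESeq2 dispersion. Shares computed from TPM in place of counts were 8.79% for the 10 most abundant genes, 1.31% for haemoglobin, 4.46% for mitochondrially encoded and 8.89% for ribosomal protein genes, and 9.56% for spike-ins, because TPM divides by length. The same transcript led in 87.2% of genes at 1 TPM and 91.1% at 20 TPM, and the median leading share was 69.9%, 71.2% and, from posterior means, 65.7%; the cause was not tested.

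Of the 638 genes over 2-fold apart (115 higher and 523 lower in replicate 2), a floor of 1 TPM gave 963 with 249 higher, and a floor of 10 TPM 73 higher. TMM-scaled CPM gave 240, 131 higher and 109 lower. Going from TPM to TMM-scaled CPM moves log2 ratios by 0.32, and going to spike-in scaling by 0.04. Deposited intervals that do not overlap left 60 higher. Subtracting the length trend, added after seeing the data, gave 264, 153 higher and 111 lower, with 206 genes shared with the 638; leaving out short or low genes, also added, left 63 higher. The cause was not tested.

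The number of lists outside the central 95% stayed at 6 or 7. Against length-matched lists the basement membrane list went from percentile 1.08 to 55.6 and branching signals from 1.16 to 17.9, while the erythroid (2.04), imprinted (99.95) and long non-coding lists (98.985) moved outside it. The podocyte list did so under TMM scaling (2.25) and the long non-coding list with members at 5 TPM (99.56). Proximal tubule genes stayed below it under every setting, at percentile 0.080 with members at 5 TPM. Among 34 list medians, FPKM moved 21 past the spread of the library medians, rescaled TPM 11, and leaving out replicate 1 or 2 6 and 4. FPKM and rescaled TPM multiply the levels of a library by a common factor. The stromal median, for example, went from 57.4 TPM to 40.6 FPKM and 67.3 rescaled TPM. Those moves are a change of scale and do not show that list levels depend on processing. The erythroid list differs, since rescaling leaves out its haemoglobin members. Leaving out a replicate is impossible for r and the dispersion, which need both. No paired analysis was possible because there is 1 group. Depth limits genes near 1 count, such as Epo.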

Other observations

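RNA that normally lacks a poly(A) tail was present and differed between the libraries. The signal recognition particle RNA genes Rn7s1 and Rn7s2, identical copies with equal values, stood at 5519.7 and 12856 TPM in replicate 1 and replicate 2, the transcription regulator Rn7sk at 371 and 650.4 TPM, the RNase P component Rpph1 at 71.5 and 217 TPM and the RNase MRP component Rmrp at 40.2 and 114 TPM. Rpph1, Rmrp and Gm26917 were chosen after their values were seen. Gm42418, a model over an 18S ribosomal RNA copy on chromosome 17, was at 13374 and 17362 TPM, and with its neighbour Gm26917 took 2.55 and 3.62 percent of gene counts. Rny3 and Rnu12 had 0 counts. Replication-dependent histone genes, whose messages end in a stem-loop, had a median of 14.2 TPM (12.6 and 16.9 TPM), which is 3.22% of the median of the polyadenylated variants, 443 TPM (426 and 460.1 TPM), and the highest members of the list were Hist1h4d at 330.5 ± 30.7 TPM and Hist1h2ae at 228 ± 39.2 TPM against H3f3a at 2358 ± 265 TPM and H2afz at 2352 ± 299 TPM. The list leaves out Hist1h2ap, a clustered histone gene that at 4354 ± 939 TPM stood above both variants, so the ratio of medians does not hold for every such gene. Whether the libraries were primed on poly(A) tails is not given in the sources used here, so the ratio cannot be read as one of message levels in the tissue. Among the long non-coding RNAs Malat1 was at 4320.3 ± 270.5 TPM, Gas5 at 650.4 ± 143 TPM and H19 at 474 ± 43.7 TPM, while Dlx6os1 had 1 and 0 counts and Hottip 0 in both.

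The comparison of Xist with Y-linked genes was planned before the data were examined, but its limits, like the 3 tests of the length trend, were written after their own result was known. The tests of the escape genes and of the nephron lists use length-matched random lists, and were written after the sex-linked genes, the unmatched list medians and the length trend had been seen but before their own percentiles were computed.

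The libraries differed in their sex-linked genes. In replicate 1 Eif2s3y stood at 42.5, Ddx3y at 37.8, Kdm5d at 24.6 and Uty at 24 TPM (7327 counts together), against 4 counts in replicate 2, whereas Xist was at 0.010 and 67.2 TPM and Tsix at 0.12 and 16.3 TPM. The higher of the Y-linked and Xist levels in the lower library was 0.0559% of the other library, which argues against RNA of both sexes in each library, although the labels call the samples pooled. Genes that escape X inactivation (Kdm6a, Kdm5c, Ddx3x, Eif2s3x and 5530601H04Rik, chosen for this test) had a median log2 ratio of 0.03, with Ddx3x (-0.36) and Kdm6a (-0.13) lower in the library with Xist, and stood at percentile 99.5 of length-matched lists, so they were high relative to genes of like length. This is consistent with 1 male and 1 female embryo and with the label of 1 pup per sample.

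Long transcripts were lower in replicate 2. The spike-ins, the same set in both samples per the labels, showed the same direction, with a slope of -0.205 per doubling of length and an upper bootstrap bound of -0.115; Pearson's r over 46 spike-ins was -0.49 (permutation p = 0.000540) and Spearman's rho -0.42 (permutation p = 0.00427), with r = -0.41 without the 2 spike-ins farthest from the median length. Over the spike-in lengths, 274 to 1994 nt, this argues against fragmentation of the tissue RNA before the spike-ins as the whole cause. No spike-in was longer, so the spike-ins cannot decide the cause for longer transcripts. Genes of 4000 to 6000 nt, for example, had a median log2 ratio of -0.65. GC content as the cause is argued against, since 98.6% of the slope was kept with it in the model. A step after the spike-ins were added, in library construction or later, is a candidate source, and a part from RNA quality of the samples stays open, as the gene slope over the same lengths was -0.267. No biological explanation was tested.

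Of the 3 lists of maturing nephron segments, that of the proximal tubule alone stood below the central range of random lists on TPM, while under TMM scaling the podocyte list did too (percentile 2.25). After subtraction of the length trend 16 of 17 members were lower, and the list stood at percentile 0 of length-matched lists, which argues against the length trend as the cause. The progenitor and renal vesicle lists were at percentiles 43.9 and 23.6, which argues against a smaller share of all nephron tissue, and 1 of the podocyte, proximal tubule and loop lists lay below the 2.5th percentile (podocyte 82.6, loop 8.78), which argues against an earlier stage of all segments. An earlier state of the proximal tubule alone, the sex of the embryo and the day of collection stay open as untested and may contribute.

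Single protein-coding genes also stood off the length trend. Of 11339 such genes with 300 or more counts in the libraries together, 19 lay at least 1.5 log2 units above the trend and 2 as far below it, with Y-linked genes and unnamed models left out; these genes and the limits were chosen after the values were seen. Besides Arpc3, the RNA-binding protein gene Raly stood at 53.6 and 231 TPM, the nucleoplasmin gene Npm3 at 16.9 and 83.5 TPM and the small GTPase gene Rac3 at 3.91 and 21.3 TPM in replicates 1 and 2. Mfsd4a (15.5 and 3.98 TPM) and Ugt2b37 (13.4 and 3.39 TPM) were those below it. The cause was not tested.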
